A study of Amphidinium carterae with 27 samples.

How the data were processed

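The series has 27 samples of the dinoflagellate Amphidinium carterae, of which 4 were compared here. These are RNA-seq libraries of cells cultured with or without 2,4-pyridinedicarboxylic acid (2-4P), with 2 libraries per group. Per the labels' protocols, cells in exponential growth were diluted to 100000 cells per ml, 2-4P was added at 0.5 mM in f/2 medium, total RNA was depleted of ribosomal RNA with a Ribo-off kit, and stranded libraries were made at 1 of 2 sequencing companies. The labels do not say which company made which library, nor how long the treatment lasted. Replicates were biological, per the series' design text. The 23 other samples (chromatin contact maps, DNA immunoprecipitation, bisulfite and chemical sequencing of DNA, a genome survey, and RNA-seq and Iso-seq for annotation) were not analysed here, so no value of 5hmU or of cytosine methylation is reported.

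The authors deposited a table of raw counts, as whole numbers, for each gene model and each annotated repeat copy in the 4 libraries. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.10a, StringTie 2.1.7 and DESeq2, without saying which step each was used for. The counting program's settings, its use of strand and its treatment of reads with several alignments are not given in the sources used here. Copies of a repeat family are near-identical and can overlap each other or a gene, so the count of a single copy is uncertain: 67.0% of annotated copies share bases with another copy. The deposited gene models come from MAKER, per the file's source column, and give identifiers without names or descriptions. The deposited repeat annotations come from RepeatMasker with a known and a de novo library, per the file headers and source columns. They hold for each copy its coordinates, its strand, its alignment score and its divergence from the library sequence it matched. That RepeatMasker score, deposited by the authors with each copy, was not used. Coordinates are those of the submitters' assembly, counted from 1, and no build name was given for it.

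All 41274 gene models and all 1673927 repeat copies in the count table were joined to these annotations, and 0 of the table's entries lacked a name. Of the gene identifiers, 0 of 41274 matched the reference table of assembly ASM5194258v1. The 17 gene lists chosen beforehand therefore could not be applied, and genes are given by identifier. The annotated span was taken as the sum over chromosomes and scaffolds of the last annotated base, since no genome sequence was used here. Bases covered by repeats were merged with bedtools 2.31.1 before they were summed. A copy that shared at least 1 base with an exon was placed in the exon class. A copy that shared at least 1 base with a gene model and none with an exon was placed in the intron class, and the remainder between genes. Copies of the exon and intron classes are called inside gene models, though they can extend beyond them. The strand of a copy was compared with that of its host gene. The strand of a de novo copy is relative to the library sequence it matched, whose own strand can be arbitrary.

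Counts were tested with edgeR 4.0.16 in R 4.3.3 using its quasi-likelihood test (glmQLFit and glmQLFTest). Genes and repeats were fitted together, with TMM factors and the filterByExpr filter at a minimum count of 10, which kept 40283 gene models and 7766 repeat copies. P values were adjusted by the Benjamini-Hochberg method over all kept features, with a threshold of 0.05. Counts of all copies of a class or superfamily, kept by the filter or not, were also summed and tested beside the gene models with the library sizes and TMM factors of the feature fit, adjusted over 105 sums. Sets of at least 10 kept copies were compared with all other features by camera (limma 3.58.1) with its preset correlation of 0.01, then with an estimated correlation, and fry tested the same sets against no change. The share of counts on repeats was compared by a two-sided exact permutation test over 6 arrangements. CPM values are counts scaled to the total of counted reads in the library, and principal components were taken on log2 CPM with a prior count of 2. Figures were drawn with matplotlib 3.10.9.

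Depth was between 13352681 and 18391595 counts per library. A count of 0 in a library allows up to 0.225 CPM in the shallowest and 0.163 CPM in the deepest (3 counts). Wilson 95% intervals are given for shares of single libraries. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

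The fits were tested on simulated counts made from the means and sizes of the real libraries, with 200 of 48049 features changed. Of these, 25 gene models and 25 repeat copies were changed at each fold size. One simulation gave all libraries of a group the same mean, and the other kept the difference between replicate numbers seen in the real libraries. In the simulation that kept it, 47193 features were fitted, and the design used here called 0 of 100 changed genes and 0 of 100 changed repeats, with 0 false calls. This included 0 of 25 genes at a 16-fold change. With genes and repeats fitted apart, an alternative added after the data were seen, it called 0 of 25 genes at 2-fold, 6 at 4-fold, 12 at 8-fold and 19 at 16-fold, and 0 of 100 repeats. A shift of all repeats by 1.5-fold was recovered with a camera p of 3.89e-39 in that simulation and of 2.07e-08 in the other. The test of the summed counts of all repeats did not recover it in that simulation (an unadjusted p of 0.173, against 0.0166 in the other), and at 2-fold it gave an unadjusted p of 0.0239 and 6.23e-13, all before adjustment over sums. Camera and fry p values come from the model across features, while an exact test of 2 libraries against 2 cannot go below 0.333. Simulated counts were drawn independently for each feature, with a common dispersion for gene models and another for repeat copies. A shift shared by many repeats of a single library was not simulated, so the power of camera in the real libraries may be lower.

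Named features followed a rule set before the data were examined. It took features past the threshold whose groups do not overlap, of which there were 0, every tested class or superfamily, and the 3 gene models and 3 repeat copies with the most counts. Any other feature named was chosen after its values were seen. Alternatives were DESeq2 1.42.0, other scalings, other filters on low counts, a fold threshold, the replicate number as a block, and each library left out in turn. The closing section gives their effect. When a library was left out, the lone library of that group was assumed to vary like the other group.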

Results

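Amphidinium carterae is a photosynthetic dinoflagellate, a group of algae in whose DNA part of the thymine is replaced by 5-hydroxymethyluracil (5hmU). The labels describe 2-4P as an inhibitor of 5hmU synthesis. The comparison of treated with untreated cells addressed whether exposure to 2-4P changes the transcripts of repeat elements, and the 5hmU level of these cells was not analysed here. Stranded RNA-seq of RNA depleted of ribosomal RNA gave 13352681 and 18110804 counts in the treated libraries (2-4P replicates 1 and 2). The untreated libraries (control replicates 1 and 2) had 15564940 and 18391595 counts. Of 41274 gene models, between 40777 and 40979 had at least 1 count in a library, and 150 had none in any. Of 1673927 repeat copies, 154101 (9.21%) had at least 1 count over the 4 libraries.

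The annotated genome was dominated by long terminal repeat (LTR) retrotransposons, which move through an RNA copy. Repeats covered 620.7 Mb, or 49.3% of the annotated span of 1259 Mb over 314 assembled sequences, 43 of them chromosomes. LTR elements covered 41.5% of that span with 1249992 copies, LINE elements (retrotransposons without terminal repeats) 5.46%, DNA transposons 3.30% and unclassified repeats 2.20%. SINE elements, which are short and depend on the enzymes of other retrotransposons, covered 0.0107%. The de novo library alone covered 48.5% and the known library alone 2.36%. Gene models spanned 64.4% of the same length with a median of 9 exons. At least 1 base was shared with a gene model by 69.7% of repeat copies, but with an exon by only 2.23%.

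By group means, LTR, LINE and DNA elements were the 3 repeat classes with the most counts in both groups, although in 2-4P replicate 1 unclassified repeats (1952 CPM) lay above DNA transposons (1939 CPM). LTR copies held 91.2% ± 0.436 (SD, n = 2) of repeat counts in treated cells and 91.4% ± 0.0604 in controls. LINE copies held 4.39% ± 0.0574 and 4.58% ± 0.0590, and DNA transposons 1.92% ± 0.161 and 1.87% ± 0.118. A few copies carried most of the signal: the 100 with the most counts held 56.4% ± 1.11 of repeat counts in treated cells and 55.9% ± 1.53 in controls. Copies within 0.5% of the library sequence they matched, 26802 in number, held 39.3% ± 2.17 and 37.6% ± 1.46. De novo library sequences such as Acart_chr38_149 carry the name of an assembled sequence. A low divergence may therefore be a match of such a sequence to its own source, which was not tested.

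**Figure D1:**
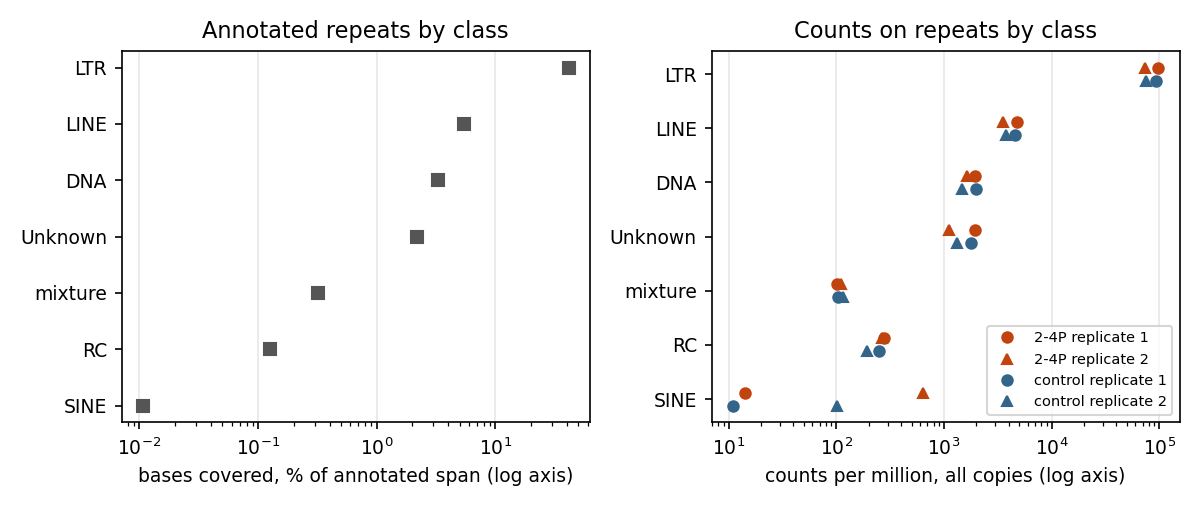
Left, bases covered by the repeat classes shown, as a percentage of the annotated span (log axis). Right, summed CPM of all copies of the class (log axis), with 1 point per library, orange for 2-4P, blue for control, circles for replicate 1 and triangles for replicate 2. LTR elements lead both panels, with 41.5% of the span, and SINE elements range from 10.9 to 641 CPM.

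Counts per Mb were higher in copies overlapping exons than in the other places. Copies overlapping exons on the strand of the gene had 3569 ± 1107 CPM per Mb of repeat in treated cells and 3613 ± 768 in controls (SD, n = 2), against 47.3 ± 5.73 and 47.3 ± 7.56 for intron copies on that strand. Copies between genes had 75.8 ± 10.8 and 67.7 ± 8.26 CPM per Mb. Copies in introns on the opposite strand had 7.08 ± 6.77 and 6.32 ± 4.99. Copies opposite to exons summed to 10286 CPM in 2-4P replicate 1 and 9558 in control replicate 1, but to 1671 and 1765 in the replicates 2, so this class differed more between replicate numbers than between treated and untreated cells.

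**Figure D2:**
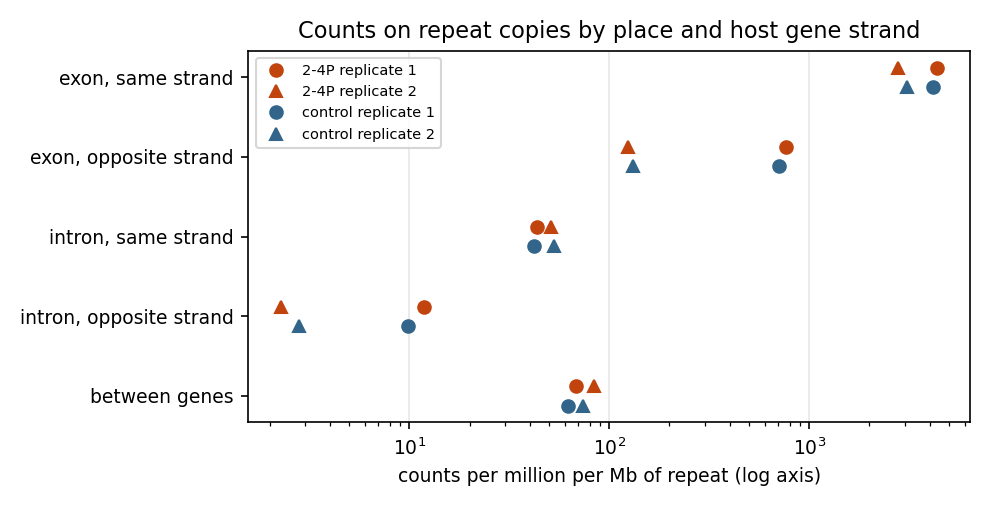
CPM per Mb of repeat (log axis) for copies by place and by strand relative to the host gene, with 1 point per library, orange for 2-4P and blue for control. Circles (replicate 1) lie above triangles (replicate 2) for copies opposite to exons or introns, while orange and blue points of the same replicate number lie close together.

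The share of counts on repeats was near 8 or 10% in all 4 libraries and differed between the groups by less than the spread within them. It was 10.7% (Wilson 95% interval 10.7 to 10.8%) in 2-4P replicate 1 and 8.06% (8.05 to 8.08%) in 2-4P replicate 2, against 10.1% (10.1 to 10.2%) and 8.21% (8.19 to 8.22%) in the controls. The group means were 9.40% ± 1.89 and 9.17% ± 1.37 (SD, n = 2), a difference of 0.231 points (two-sided exact permutation p = 1.0, where 6 arrangements allow no p under 0.333). Within replicate number 1 the treated library was higher by 0.603 points, and within number 2 the difference was -0.141 points. The sign of the group difference turned when 2-4P replicate 1 (-1.11 points) or control replicate 2 (-0.735 points) was left out. Either comparison sets 1 library against 2 of unlike number. Copies overlapping exons held 60.5% of repeat counts in treated cells and 62.9% in controls. Without them, an alternative chosen after the data were seen, the share was 3.61% and 4.02% in 2-4P replicates 1 and 2. It was 3.32% and 3.76% in control replicates 1 and 2, so the treated library was then higher within both numbers (exact permutation p = 0.667).

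In the fit by treatment group alone, no repeat class or superfamily passed the test for a difference between treated and untreated cells. The summed counts of LTR elements were 85817 ± 17673 CPM in treated cells and 83822 ± 12431 in controls (SD, n = 2), a log2 fold change of 0.05 ± 0.27 (SE). LINE elements had 4136 ± 885 and 4195 ± 571 CPM, and DNA transposons 1789 ± 212 and 1728 ± 364. Most LTR counts lay on copies with no assigned superfamily, with a mean of 77939 CPM in treated cells and 76149 in controls. Among named LTR superfamilies, Copia elements had 4382 ± 7.51 and 4273 ± 143 CPM and Gypsy elements 1975 ± 111 and 1820 ± 23.6. Rolling-circle elements (RC, mostly Helitrons) had 271 ± 9.99 CPM in treated cells and 222 ± 40.3 in controls, a log2 fold change of 0.30 ± 0.22.

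Of 105 sums tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05 and 0 had an unadjusted p under 0.05, with the lowest unadjusted p at 0.111 and the lowest adjusted p at 0.999. DESeq2 also called 0 sums. This test has limited power, since a simulated 1.5-fold shift of all repeats gave their sum an unadjusted edgeR p of 0.173 with the difference between replicate numbers kept. The 95% intervals were -0.59 to 0.70 for LTR, -0.63 to 0.63 for LINE, -0.55 to 0.68 for DNA and -0.24 to 0.83 for RC elements on the log2 scale, so that a 2-fold change of any of these sums lay outside its interval. Within replicate numbers 1 and 2, the log2 ratio of treated to control was 0.11 and -0.02 for LTR, 0.07 and -0.10 for LINE, -0.01 and 0.17 for DNA, and 0.17 and 0.45 for RC elements.

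SINE elements gave a wide interval. Their log2 fold change was 2.56 ± 1.55 (SE, interval -1.17 to 6.28, edgeR adjusted p = 0.999), from 14.3 and 641 CPM in treated replicates 1 and 2 and 10.9 and 100.5 in the controls. The ratio within number 1 was 0.41 and within number 2 it was 2.68 (log2). A single copy held most of these counts in both replicates 2, TE244938, a 543-base match to MeloSINE between genes on Acart_chr08 (384127 to 384669, plus strand), with 8.46, 630.1, 5.33 and 90.1 CPM in 2-4P replicates 1 and 2 and control replicates 1 and 2. It was chosen after its values were seen, and it lies in a cluster with matches to R2, an element that inserts into ribosomal RNA genes. Whether sequences of this cluster are repeats or ribosomal DNA was not tested, since no genome sequence was used here. The log2 fold change of SINE elements was 3.52 without 2-4P replicate 1 and -1.87 without 2-4P replicate 2. It was 1.72 without control replicate 1 and 4.81 without control replicate 2. Each of these fits sets 1 library against 2 of unlike number and can carry the difference between numbers. Without the copies of the cluster, an alternative chosen after the data were seen, the log2 fold change of SINE elements over all libraries was -0.014.

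**Figure D3:**
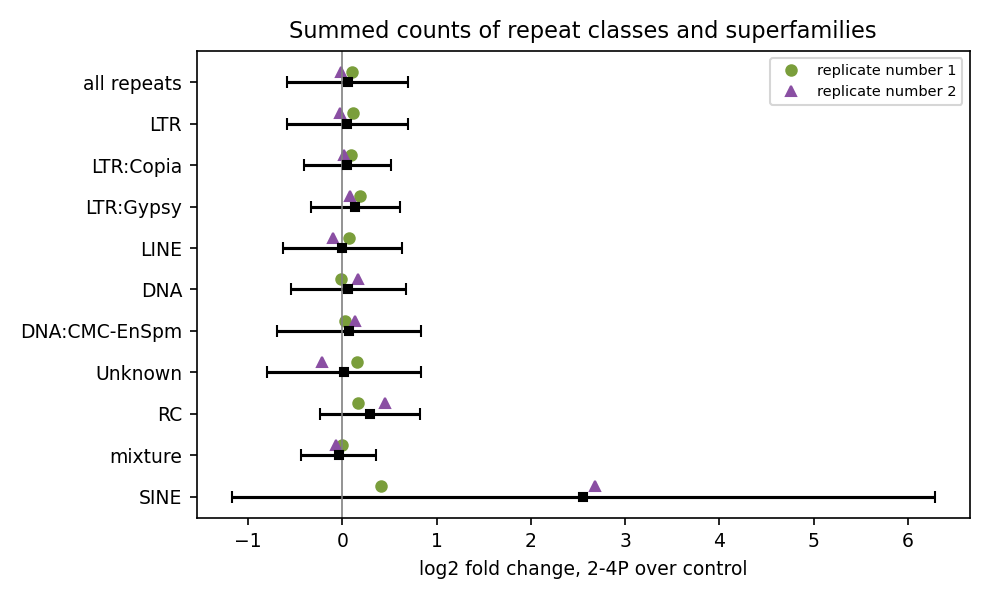
Log2 fold change of summed counts, 2-4P over control, for all repeats, the classes with the most counts and the superfamilies Copia, Gypsy and CMC-EnSpm. Some superfamilies with more counts than CMC-EnSpm are not shown. Black squares with bars are the edgeR estimates with 95% intervals, green circles and purple triangles the ratios within replicate numbers 1 and 2. Each interval includes 0, and the SINE interval runs from -1.17 to 6.28.

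In the same fit by group alone, no gene model and no repeat copy passed the test for a difference between treated and untreated cells. The 3 gene models with the most counts had nearly equal levels in both groups. Acart31G0311 (Acart_chr31, 6481131 to 6618408, minus strand) had a log2 fold change of 0.02 ± 0.31 (SE), with 1458 and 965 CPM in treated and 1365 and 1069 CPM in control replicates 1 and 2. Acart10G0029 (Acart_chr10, 898161 to 919412, minus strand) had -0.02 ± 0.20, and Acart22G0838 (Acart_chr22, 24611718 to 24626269, minus strand) had -0.01 ± 0.22.

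The 3 repeat copies with the most counts were de novo LTR elements. TE0157273 lay between genes on Acart_chr08 (372296 to 376911, plus strand) and had 697 and 6091 CPM in treated and 385 and 4026 CPM in control replicates 1 and 2, a log2 fold change of 0.63 ± 1.34 (SE), and it lies in the cluster that also holds the R2 matches and TE244938. TE1273055, which overlaps an exon on the strand of its gene on Acart_chr16 (316183 to 317090, plus strand), had 3936 and 403 CPM against 3189 and 695, with a log2 fold change of 0.19 ± 1.23. TE0098416, which overlaps exons of genes on both strands of Acart_chr13 (23260978 to 23285801, plus strand), had 2352 and 1436 CPM against 2344 and 1426, with a log2 fold change of 0.02 ± 0.40. Each of these 3 copies differed more between replicate numbers than between treated and control libraries of the same number.

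edgeR called 0 of 40283 gene models and 0 of 7766 repeat copies at an adjusted p of 0.05, with the lowest adjusted p at 0.999997. At an unadjusted p under 0.05 there were 105 gene models (93 higher and 12 lower with 2-4P) and 38 repeat copies (25 higher and 13 lower). These counts moved with the library left out, but each such fit sets 1 library against 2 of unlike number. Such a fit can therefore carry the difference between numbers. With all 4 libraries, DESeq2 also called 0 gene models and 0 repeat copies, with 37 gene models and 29 repeat copies at an unadjusted p under 0.05. The median log2 fold change was 0.00386 for gene models and 0.02 for repeat copies. The 95% interval of 71.6% of gene models, but of only 8.65% of repeat copies, excluded a 2-fold change in both directions. Without the filter on low counts, edgeR called 18 gene models, all higher, and 38 repeat copies, 10 higher and 28 lower, of which 18 had no count in 1 of the groups. Most of these 18 copies had counts in a single library, so their absence from a group rests on that library. An example is TE0527654, with 0 and 0 counts in 2-4P replicates 1 and 2 and 0 and 1717 in control replicates 1 and 2. False calls of the fit without the filter were not simulated.

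The fit by group alone had little power for single features, as 0 of 25 simulated genes with a 16-fold change, and 0 of 100 changed repeats, were called by it. For gene models this low power was that of the fit. With the replicate number as a block, 96 of 100 changed genes and 2 unchanged ones were called in the simulation that kept the difference between numbers. In the real libraries the block gave 0 gene models, and the closing section gives its limits. With genes and repeats fitted apart, a fit added after the data were seen that called 0 of 25 simulated genes at 2-fold, 6 at 4-fold and 19 at 16-fold, edgeR again called 0 gene models, with 175 at an unadjusted p under 0.05. That fit also called 0 of 100 changed repeats, so its 0 repeat copies (14 at an unadjusted p under 0.05) say nothing about changes in single copies.

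Repeats as a set showed no shift relative to genes that passed the test. Their median log2 fold change was 0.02, and camera, fitted with edgeR, gave the direction as lower with p = 0.523 (p = 0.650 with an estimated correlation), while fry, which tests a set against no change and not against genes, gave p = 0.949 with the direction as higher. Over 34 sets, 0 passed an adjusted p of 0.05 with either correlation. The lowest camera p values were those of Helitrons, with a median log2 fold change of 0.18 over 36 copies (camera p = 0.00489, adjusted p = 0.166, adjusted p = 0.992 with an estimated correlation), and of the RC class that contains them, with 0.15 over 41 copies (p = 0.0145, adjusted p = 0.246). The lowest of the 34 fry p values, which were not adjusted, was that of the Pao superfamily of LTR elements (a fry p of 0.00964, lower with 2-4P), where the mean log2 fold change was -0.51 and the median 0.04 over 42 copies and the camera adjusted p was 0.424. The summed counts of Pao elements were 465 ± 101 CPM in treated cells and 476 ± 48.3 in controls (SD, n = 2).

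Copies inside gene models and copies between genes showed no difference in response that passed the test. Medians were -0.00018 (log2) over 5045 copies inside gene models and 0.04 over 2721 copies between genes, a difference of -0.04 (a camera p of 0.172, adjusted 0.344). Copies overlapping exons had 0.04 and those in introns -0.04, and 0 of 8 place and strand sets passed. The set test and the difference by place both turned with the library left out, but each such fit sets 1 library against 2 of unlike number. Such a fit can therefore carry the difference between numbers. The median log2 fold change of repeat copies was 0.12 without 2-4P replicate 2 and -0.13 without control replicate 2. It was -0.12 without 2-4P replicate 1 and 0.09 without control replicate 1. In the same order of left-out libraries, the difference by place was 0.31, -0.46, -0.38 and 0.18 (log2).

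On the first principal component, libraries separated by replicate number and not by treatment. This component of log2 CPM held 84.9% of the variance and placed both replicates 1 at -102.3 and -104.5 and both replicates 2 at 112.4 and 94.5. Between numbers 2 and 1, edgeR called 5440 gene models (2761 higher and 2679 lower in number 2) and 3339 repeat copies (979 higher and 2360 lower), against 0 and 0 between treated and control libraries. These counts come from fits of unlike power. In the fit by treatment the difference between numbers counts as spread within groups. The common biological coefficient of variation was 0.350 in that fit and 0.119 in the fit by number. The biological coefficient of variation between the libraries numbered 1 was 4.41% for gene models and 18.9% for repeat copies, and between those numbered 2 it was 14.8% and 28.3%. Between the treated replicates it was 23.3% and 110.0%, and between the control replicates 18.5% and 108.8%. Repeat copies opposite to exons differed most often, with 1544 of 1599 lower in number 2 and a median log2 fold change of -5.66.

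**Figure D4:**
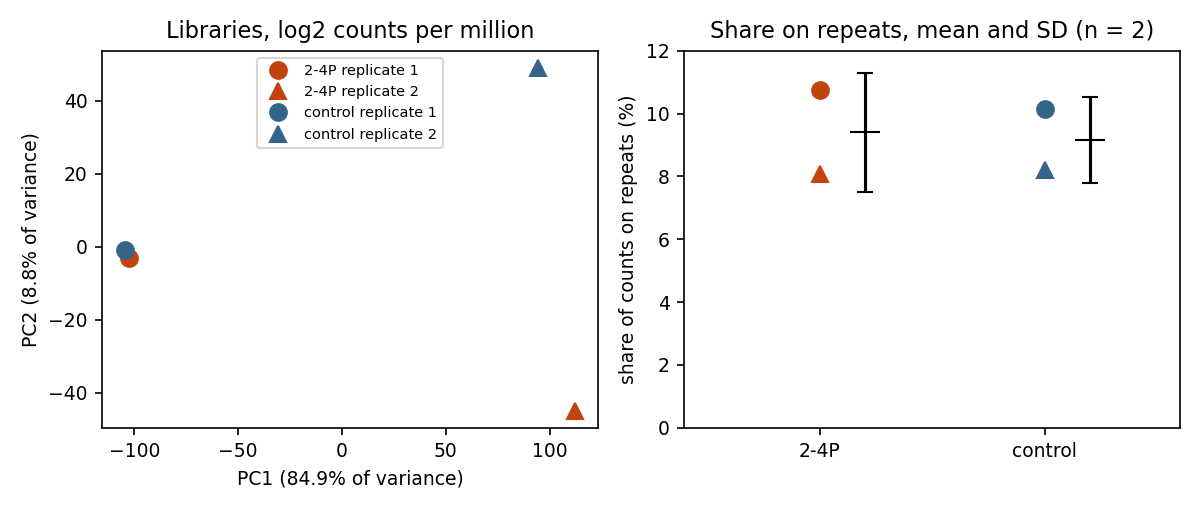
Left, the 4 libraries on the first 2 principal components of log2 CPM of kept features, which hold 84.9% and 8.77% of the variance. Right, the share of counts on repeats in each library, with the mean and SD of each group (n = 2) beside it. Replicates with the same number lie together on the first component, and the group means of 9.40% and 9.17% lie within an SD of each other.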

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

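Alternatives that merged overlapping copies, left out the cluster on Acart_chr08 and Acart_un69, left out copies that are opposite to genes or overlap exons, or fitted genes and repeats apart were chosen after the data were seen. Of 17 alternatives, 16 gave 0 gene models and 15 gave 0 repeat copies, and 11 of 13 gave 0 class sums. Without the filter on low counts there were 18 gene models and 38 repeat copies. Fisher's exact p for their directions was 1.24e-07, which only describes the calls, since features are not independent replicates. In that setting the set test gave a camera p of 0.771 (higher) and the difference by place was 0. All 18 gene models and 19 of the 38 copies pass the filter, and the gene models have a median log2 ratio of 0.37 within number 1 and 1.68 within number 2. The balance of higher and lower calls was computed in this setting only, since no other called gene models, and the gene lists were not run. At an unadjusted p under 0.05 there were 752 gene models and 349 repeat copies without the filter and 53 gene models with scaling to library totals, against 105 and 38, and 24 repeat copies after merging overlaps. Scaling to library totals gave -0.0064 (log2) for unclassified repeats and -0.0059 for Acart31G0311, leaving out copies opposite to genes gave -0.018 for unclassified repeats, leaving out the cluster gave -0.014 for SINE elements, and fry, which tests repeats against no change and not against genes, gave a p of 0.949 (higher). RC elements stayed higher in 13 of 13 alternatives. Annotated repeats covered 59.2% of the span without merging overlaps, 2.36% with the known library and 48.5% with the de novo library. The cause was not tested for these changes, except that known and de novo libraries hold fewer copies and unmerged overlaps are counted repeatedly.

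With each library left out in turn, 0 gene models and 0 repeat copies were called, and 0 to 2 class sums. Log2 fold changes ran from -0.23 to 0.28 for all repeats, -0.24 to 0.28 for LTR, -0.30 to 0.24 for LINE, -0.19 to 0.35 for DNA, -0.51 to 0.39 for unclassified, 0.07 to 0.55 for RC and -1.87 to 4.81 for SINE elements. They ran from -0.38 to 0.31 for Acart31G0311, -0.19 to 0.15 for Acart10G0029, -0.18 to 0.18 for Acart22G0838, -1.56 to 3.05 for TE0157273, -2.34 to 1.75 for TE1273055 and -0.45 to 0.49 for TE0098416. The set test ran from a camera p of 1.33e-05 to 0.712, the difference by place from -0.46 to 0.31, and the share of counts on repeats from -1.11 to 1.57 points. Each of these fits sets 1 library against 2 of unlike number.

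The labels share the numbers 1 and 2 between the groups without saying that a number marks a batch. Deviations from the group means of same-numbered libraries correlated across features (r = 0.683 for gene models and 0.878 for repeat copies, which are not independent replicates). With the replicate block, edgeR called 0 gene models, 8 repeat copies (3 higher and 5 lower) and 2 class sums. At an unadjusted p under 0.05 there were 2373 gene models (2038 higher) and 440 repeat copies (289 higher). The 3 higher of the 8 called copies, TE0157270, TE0157274 and TE1248193, lie in the cluster on Acart_chr08 and Acart_un69. The sums were SINE elements with a log2 fold change of 1.85 (adjusted p = 0.00127) and their superfamily SINE:SINE with 2.18 (adjusted p = 0.000103). Unclassified repeats had -0.028, Acart31G0311 -0.0097 and TE1273055 -0.22 in that fit. In simulated data that kept the structure of the numbers it called 56 of 100 changed repeats and 94 unchanged ones, and 96 of 100 changed genes with 2 unchanged. With the block, 4 copies were called after merging overlaps and 0 gene models and 0 copies with genes and repeats fitted apart, a fit that called 98 of 100 simulated genes but 36 of 100 simulated repeats. Of all annotated copies, 90.8% had no count in any library, and whether depth sets this share was not tested.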

Other observations

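The tests of strand leakage in repeat copies opposite to exons, of strand leakage as the cause in other repeat copies and other gene models, of overlapping copies, and of a change shared by both replicate numbers were chosen after the result was seen.

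A cluster of 145 repeat copies between genes, on Acart_chr08 (340000 to 400000) and the scaffold Acart_un69, differed in level by replicate number. It summed to 983 CPM in 2-4P replicate 1, 526 in control replicate 1, 10181 in 2-4P replicate 2 and 6124 in control replicate 2, so the treated library was 1.87 times the control within number 1 and 1.66 times within number 2. The cluster holds TE0157273, the repeat copy with the most counts, and TE244938, the SINE copy that set the class value. It also holds 65-base matches to R2B_DM, an R2 element, a family of LINE elements that insert into ribosomal RNA genes. The copy TE0157274, next to TE0157273 on the plus strand (376911 to 378988), had 0, 18885, 2 and 1215 counts in 2-4P replicates 1 and 2 and control replicates 1 and 2. With the filter on low counts, edgeR called none of the cluster's members for treatment in the fit by group alone, as it called 0 of 7766 copies. Without the filter it called TE0157270 (adjusted p = 3.95e-05), TE0157274 (adjusted p = 2.44e-30) and TE244938 (adjusted p = 1.05e-17), all higher with 2-4P. It called TE0157282, on Acart_chr08 outside these bounds, lower (adjusted p = 3.97e-15, with 0, 0, 0 and 176 counts). These p values cannot be read as the spread between replicates, since TE244938 had 113 and 11411 counts in 2-4P replicates 1 and 2. In the same edgeR fit, TE0523911 had an adjusted p of 8.31e-115 from 0, 2210, 0 and 2 counts. False calls without the filter were not simulated. Whether the cluster is ribosomal DNA annotated as repeats was not tested, and ribosomal RNA depletion was not measured.

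The libraries split by replicate number in 5440 gene models and 3339 repeat copies. Of the differing features, 93.0% still differed after thinning to the smallest library. Without the 100 features with the most counts, 99.5% of the differing gene models still did. The fit already scaled libraries by size and TMM factors, so neither test could easily have removed most calls, and they decide little about depth or abundant features. Exonic length explained 2.82% of the variance of gene changes. Leakage of antisense reads in the libraries numbered 1 may account for copies opposite to exons: their median count was 9.28% and 9.47% of that expected from the host gene in the replicates 1 and 0% in both replicates 2, and gene models opposite to another gene's exon differed 2.53 times as often as others (33 of 97, 28 of them lower in number 2). It cannot account for the whole split, since 27.5% of the kept copies that are between genes or on their gene's strand and 13.5% of all other gene models also differed. The 2 sequencing companies named in the labels, or separate cultures, cannot be told apart as a source because the labels tie neither to a library, and a biological difference between cultures was not tested.

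A set of 19 repeat copies had no count in both libraries of 1 treatment group and at least 5 counts in each of the other, 12 absent with 2-4P and 7 absent in controls. The split by number gave 2150 such copies and the crossed split 43, so the treatment split does not stand out. Reads assigned to a different one of several overlapping copies are a candidate explanation, as 78.9% of the 19 share bases with another copy (15 copies, exact 95% interval 54.4 to 93.9%) and in 10 of those 15 the summed count of the overlapping copies lay within 2-fold between the groups. The share found for all copies lies inside that interval, so the overlap stays open as an explanation, and so does a loss or gain of transcripts with 2-4P, which was not tested.

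Changes with 2-4P were weakly shared between the replicate numbers among gene models. Of 701 gene models that changed by over 0.5 (log2) within both numbers, 428 (61.1%) changed the same way, 322 of them higher and 106 lower. The share expected from the directions of these 701 gene models within each number is 54.5%. Across all 40283 gene models the changes correlated with r = 0.0826, and genes are not independent replicates. Among repeat copies, 469 of 1002 (46.8%) changed the same way, against 49.8% expected from their directions within each number. Across all repeat copies the changes correlated with r = -0.0565. The share among gene models could reflect a small response of some genes in both numbers, a hypothesis that more replicates would have to test. A technical difference between treated and control libraries that recurred in both numbers was not tested.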
